A study of Caenorhabditis elegans with 8 samples.

How the data were processed

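Total RNA from whole adult animals of 4 strains, each fed and fasting, was measured on 8 Affymetrix C. elegans arrays. Per the labels' protocols, RNA was extracted with Trizol, labelled with biotin by 3-prime in vitro transcription and hybridised, with 1 array for each of the 8 combinations of strain and food. The deposited values are array intensity on a linear scale, in a single table of 22625 probe sets, and the authors' method of summarising and normalizing them is not given in the sources used here. The table's range and the close array medians (35.1 to 37.7) show a linear scale with arrays brought to a common level, while background treatment stays unknown. The values were used as deposited, without further normalization.

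The 77 control probe sets were left out of the tests and used as quality values. The other 22548 were transformed as log2(intensity + 16), which understates the change of dim genes, and the 30% of them with the lowest mean over the arrays were left out, those below an intensity of about 15.71, which left 15783. Gene names came from the platform annotation table given with the series, updated by Entrez number to the RefSeq names of assembly WBcel235. Of the 22548 probe sets, 20766 had 1 symbol there, 887 had several and 895 were not listed, and 20701 symbols were matched while 65 were kept as given. Genes were named from probe sets with 1 symbol, using for each of 11975 genes the probe set with the highest mean. Of 2389 genes with several probe sets tested, 1 had a called probe set and another that moved by more than 0.5 the other way in fasting. Probe sets shared by near-identical genes can mix their signals.

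The main model was additive, strain plus food over all 8 arrays, fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend in the empirical Bayes step (residual degrees of freedom 3, prior 3.721). Fasting was tested as the mean change over the 4 strains, with strain as a block, and each mutant was tested against wild type with food as a block. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The p-values measure only the spread between these 8 arrays around the additive model, which holds differences in response between strains and may also be technical. Changes within 1 strain were counted at 2-fold without a test. Differences in response between strains were described by correlation and slope over probe sets, and by shares of probe sets chosen in the strains outside the comparison.

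A total of 44 gene lists, fixed before the data were examined, covered metabolism, stress, immunity, protein turnover, small RNA pathways and tissues. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists (for the mutants over the lists and the 3 mutants together). Calls of single list members were also counted adjusted over the list alone. For single strains, the median of a list was ranked among 10000 random lists of the same size matched on mean expression. Named genes followed a rule fixed beforehand. After the targeted genes it took the 12 largest rises and 12 largest falls in fasting, 8 each way for each mutant (the 4 largest by size where fewer than 4 passed), 5 each way for each strain, 6 each way for differences in response, and up to 4 members of a list. Genes ranked for fasting also had to move the same way in all 4 strains, and those ranked for a mutant the same way fed and fasting.

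Alternatives fixed beforehand were no filter or a 50% filter on dim probe sets, quantile normalization, centring on array medians, a pseudocount of 1 or 64, no mean-variance trend, limma's arrayWeights, leaving out strain or food from the model, leaving out single arrays or strain pairs, a 3-fold threshold, probe sets chosen by wild type, the mean of a gene's probe sets in the list tests, and an adjusted p under 0.01 for shared calls. Fits without the drsh-1 pair for the other mutants, without the daf-16 fasting array, list tests without the drsh-1 or daf-16 pair, and tests of each strain's response against the other 3 were added after seeing the data. Weights of the arrays were 1.58 for each wild-type array, 0.424 for drsh-1, 3.55 for ain-1 and 0.42 for daf-16. In this model the residuals of the 2 arrays of a strain mirror each other, so both get the same weight. The weights thus follow how far a strain's change departs from the mean change, and cannot separate this from array quality.

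The steps were tested on simulated data with 50 probe sets changed at each fold among 15783. For fasting, 58% of 1.5-fold changes, 92% of 2-fold and 98% of 3-fold changes were recovered, with 15 false calls among 189. For drsh-1 these were 26%, 70% and 92% (10 false of 154), for ain-1 20%, 76% and 92% (8 of 152), and for daf-16 20%, 74% and 94% (7 of 151). Each simulated fasting change was the same in all 4 strains, each mutant change the same fed and fasting, and residuals were drawn independently. These rates therefore do not hold for responses that differ between strains, which count as error in the real data. In 20 simulations with no effect, at most 1 of the 44 lists was called. That count holds only for genes as simulated. The correlation between genes estimated in the data was 0.369 for collagens, 0.587 for sperm and 0.792 for oocyte genes. Lists with such correlation were not tested by simulation. The count therefore cannot show that camera with a preset correlation keeps its error rate for them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.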

Results

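Messenger RNA was measured in whole adult Caenorhabditis elegans of 4 strains, each with food and without it. The strains were wild type N2 and the mutants drsh-1(ok369), ain-1(tm3681) and daf-16(mu86). DRSH-1 is Drosha, the nuclear enzyme that cuts primary microRNA transcripts. AIN-1 is a GW182 protein of the microRNA silencing complex, and DAF-16 is the FOXO transcription factor downstream of insulin signalling. The question stated for the series is what part the microRNA machinery has in gene expression under fasting and in longevity. Animals grew at 20 °C and were placed on day 2 on plates with or without killed bacteria, in the presence of FUDR, which blocks progeny. Adults of day 4 were collected for Affymetrix C. elegans arrays. Each of the 8 groups had 1 array, so no group had replicates, and the number of arrays limits the precision of every value. Median intensities over the probe sets lay between 35.1 and 37.7 on the 8 arrays.

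The targeted genes were read first. In drsh-1 animals 1 probe set of drsh-1 had an intensity of 14 fed and 17.1 fasting, against 182.8 and 185.2 in wild type. A second probe set of drsh-1 was 5.78 times the wild-type level in fed drsh-1 animals and 5.19 times in fasting ones, with 68.7 in wild type fed and 397 in drsh-1 fed. Of the daf-16 probe sets, 1 was at 9.3 fed and 9.0 fasting in daf-16, against 76.4 and 69.5 in wild type, and its other 3 probe sets were at 0.371 to 0.763 times wild type. The 3 probe sets of ain-1 were at 0.72 to 0.992 times wild type in ain-1. Where the probes lie relative to the deletions is not given in the sources used here, so the ain-1 probe sets check nothing about that label.

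Single genes changed with fasting in both directions over the 4 strains together. Intensity of sysm-1, which encodes a secreted ShK-domain immune effector, went from 2101 fed to 12 fasting in wild type, and it was 36.8-fold lower over the strains (log2 change −5.20 ± 0.45, SE, adjusted p = 0.0034). The value of 12 lies below 15.71, the level of the filter, so the pseudocount limits the size of that fall. The lysozyme gene ilys-5 fell by 4.96 ± 0.27 (adjusted p = 0.00087), from 7783 to 188 in wild type and from 1590 to 96 in drsh-1. Among genes that rose, the aquaporin gene aqp-1 gained 2.40 ± 0.43 (5.27-fold, adjusted p = 0.038), from 67 to 885 in wild type. The fatty acid and retinol binding protein gene far-7 gained 2.21 ± 0.36 (4.61-fold, adjusted p = 0.027), from 20 to 215 in wild type.

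Of 15783 probe sets tested with limma, 68 were higher and 455 lower in fasting at an adjusted p under 0.05, which are 52 and 359 genes. These counts depended on the model, with 3680 higher and 2662 lower under arrayWeights and 4 and 125 without the strain block, so the balance of directions is not settled. At an unadjusted p under 0.05 there were 4742, where 789 were expected by chance. The other lowest genes were hrg-11.2 (−4.71 ± 0.35), dod-19 (−4.58 ± 0.74), the cathepsin A homologue ctsa-1.2 (−4.55 ± 0.23), C17H12.8 (−4.32 ± 0.31), nspg-13 (−3.95 ± 0.43), the lysozyme gene lys-2 (−3.89 ± 0.22), irg-7 (−3.80 ± 0.31), drd-50 (−3.78 ± 0.26), the folate transporter gene folt-2 (−3.74 ± 0.41) and nspg-9 (−3.68 ± 0.31), with adjusted p from 0.00087 to 0.027. The other highest genes were dct-7 (2.09 ± 0.41), the C-type lectin gene clec-266 (1.91 ± 0.37), the neuropeptide gene nlp-51 (1.87 ± 0.33), the linker histone gene hil-1 (1.71 ± 0.34), F15E6.3 (1.61 ± 0.29), scl-2 (1.61 ± 0.31), Y43C5A.3 (1.61 ± 0.30), T22B7.3 (1.59 ± 0.16), F45D3.4 (1.58 ± 0.28) and nlp-39 (1.36 ± 0.24), with adjusted p from 0.0054 to 0.049. The rule took only genes that moved the same way in all 4 strains, so this agreement was set by the choice. The strains stood in for replicates, so a response that differed between strains counted as error. Without the drsh-1 pair of arrays the calls were 2361 higher and 1415 lower, and the 523 calls over 4 strains were among these in the same direction. Without the wild-type pair they were 3 higher and 105 lower, without the ain-1 pair 3 and 112, and without the daf-16 pair 3 and 94.

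**Figure D1:**
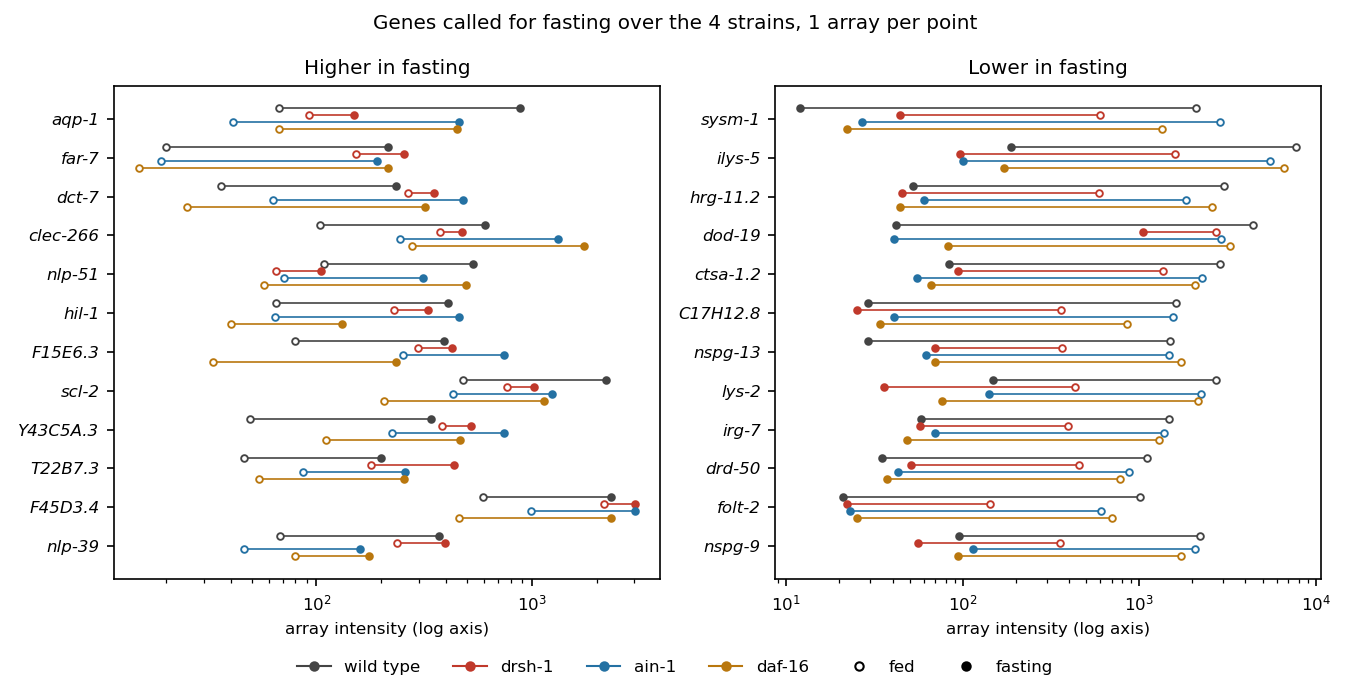
Array intensity on a log axis of the 12 genes with the largest rise and the 12 with the largest fall among those called for fasting over the 4 strains, with 1 open point (fed) and 1 filled point (fasting) per strain joined by a line. In drsh-1 the rise of aqp-1 went from 92 to 150 where wild type went from 67 to 885, while sysm-1 in drsh-1 went from 598 to 44.

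Collagens, muscle genes and intestinal genes were lower in fasting by camera with a preset correlation, but not with an estimated correlation, as lists fixed before the data were examined. Of 127 collagens measured, 34 fell and 0 rose over all genes tested, and 60 fell and 2 rose adjusted over the list alone. The examples were col-143 (5642 to 809 in wild type, −3.21 ± 0.23), col-160 (−2.97 ± 0.22), col-159 (−2.96 ± 0.28) and col-8 (−2.78 ± 0.26). Of 30 muscle genes, 11 fell (21 adjusted over the list alone, with 1 higher), among them the troponin I gene unc-27 (−1.49 ± 0.18), clik-1 (−1.45 ± 0.18), the troponin T gene tnt-2 (−1.4 ± 0.20) and the myosin gene unc-54 (754 to 249 in wild type, −1.33 ± 0.17). Of 21 intestinal genes, 6 fell (12 adjusted over the list alone), with the intermediate filament genes ifb-2 (−1.66 ± 0.14) and ifc-2 (−1.60 ± 0.19) and the microvillar actin gene act-5 (−1.56 ± 0.22). By camera with a preset correlation the adjusted p was 1.1e-21 for collagens, 1.8e-09 for muscle and 4.5e-06 for intestine. These were adjusted p = 0.65, 0.63 and 0.30 with an estimated correlation, and the intestine list also passed fry (adjusted p = 0.013). Neuronal genes (31 measured, 1 lower) had a median change of −0.02.

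Lists of lysosomal proteases and V-ATPase, of lysozymes and caenopores, and of C-type lectins were lower in the same comparison by camera, again with a preset correlation only. Of 46 lysosomal protease and V-ATPase genes, 9 fell (19 adjusted over the list alone, with 1 higher), led by the aspartyl protease gene asp-17 (507 to 28 in wild type, −3.26 ± 0.17), the cathepsin B-like genes cpr-5 (−1.75 ± 0.25) and cpr-9 (−1.69 ± 0.24), and asp-13 (−1.32 ± 0.21). Of 24 lysozymes and caenopores, 8 fell and 1 rose (13 and 4 adjusted over the list alone). Besides ilys-5 and lys-2, lys-7 went from 7530 to 704 in wild type (−3.46 ± 0.33) and lys-1 fell by 2.29 ± 0.22, while ilys-2 rose by 1.24 ± 0.12 (adjusted p = 0.0055). Both lists passed camera with a preset correlation (adjusted p = 7.4e-06 and 0.00015) and fry (adjusted p = 0.013 each), and each had adjusted p = 0.30 with an estimated correlation. Of 98 C-type lectins, 13 fell and 2 rose (20 and 3 adjusted over the list alone), including clec-41 (−3.39 ± 0.49), clec-50 (−2.65 ± 0.31), clec-173 (−2.49 ± 0.42) and clec-85 (−2.45 ± 0.31). The camera adjusted p for lectins was 0.0021, with adjusted p = 0.69 with an estimated correlation, and the median member moved by −0.05.

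Some lists of detoxification, lipid synthesis and reproduction were also lower with a preset correlation only, while cytochromes P450 (45 genes, median −0.01) and oxidative and xenobiotic stress (23 genes, median 0.03) did not pass (camera adjusted p = 0.64 each). Of 48 UDP-glucuronosyltransferases, 9 fell (21 lower and 5 higher adjusted over the list alone), with ugt-26 (−2.38 ± 0.22), ugt-22 (−2.16 ± 0.19) and ugt-44 (−1.58 ± 0.16), and of 28 glutathione S-transferases 4 fell and 1 rose (6 and 4 adjusted over the list alone). Of 25 genes of fatty acid synthesis and desaturation 4 fell, also adjusted over the list alone: acs-1 (−2.3 ± 0.35), the stearoyl-CoA desaturase gene fat-7 (−2.24 ± 0.42), elo-5 (−1.44 ± 0.21) and dgat-2 (−1.39 ± 0.22). Of 5 yolk protein genes vit-1 fell (2311 to 408 in wild type, −2.61 ± 0.18), and 5 were lower adjusted over the list alone. Median changes were −0.30 over 42 sperm genes (1 fell, over all genes and adjusted over the list alone), −0.34 over 32 oocyte and eggshell genes and −0.22 over 41 germline genes, with 0 calls by limma in the last pair of lists on either adjustment. These medians were uneven between strains: sperm genes had −0.92 in ain-1 and −0.14, 0.07 and −0.21 in wild type, drsh-1 and daf-16. Germline genes had −0.57 in daf-16, whose fasting array had odd controls, and −0.08, 0 and −0.11 in wild type, drsh-1 and ain-1, while oocyte genes had −0.73 against −0.19, −0.07 and −0.38. Genes that DAF-16 is known to lower (class II, 15 measured) had 2 lower, 7 adjusted over the list alone. The camera adjusted p of these lists ran from 3.9e-07 for oocytes to 0.036 for glutathione S-transferases, and with an estimated correlation they had adjusted p = 0.63 to 0.76.

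Lists that were higher in fasting, with a preset correlation only, held few single genes past the threshold. Of 27 histone genes 1 rose, hil-1, and 15 were higher adjusted over the list alone, with his-71 at 1.29 ± 0.28 and his-24 at 0.80 ± 0.21 (adjusted p = 0.060 and 0.077 over all genes). The 26 autophagy genes had 0 calls by limma over all genes, 12 higher adjusted over the list alone, and a median change of 0.39, with epg-2 at 1.29 ± 0.32 and sqst-1 at 0.70 ± 0.20. The 18 SKP1-related genes, which encode parts of ubiquitin ligases, had 0 calls over all genes, 11 higher and 1 lower adjusted over the list alone, and a median of 0.65, with skr-10 at 1.51 ± 0.34 and skr-8 at 1.41 ± 0.28. Of 28 genes that DAF-16 is known to raise (class I) 2 rose and 2 fell (6 and 3 adjusted over the list alone), and their median was 0.38. Small shifts upward were found for 39 respiratory chain genes (median 0.18), 162 F-box genes (0.16), 141 nuclear hormone receptors (0.11), 38 translation factors (0.19), 77 ribosomal proteins (0.06), 34 proteasome genes (0.12) and 24 genes of endoplasmic reticulum stress (0.16). The 11 lists higher by camera with a preset correlation had adjusted p from 4.3e-05 for histones to 0.026 for class I. They had adjusted p = 0.69 to 0.73 with an estimated correlation, and 0 of them passed fry. The microRNA machinery (24 genes, camera adjusted p = 0.56) and the targets of lin-4 and let-7 (13 genes, adjusted p = 0.87) did not pass, nor did mitochondrial beta-oxidation (26 genes, camera adjusted p = 0.75) or the heat shock response (18 genes, adjusted p = 0.15).

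**Figure D2:**
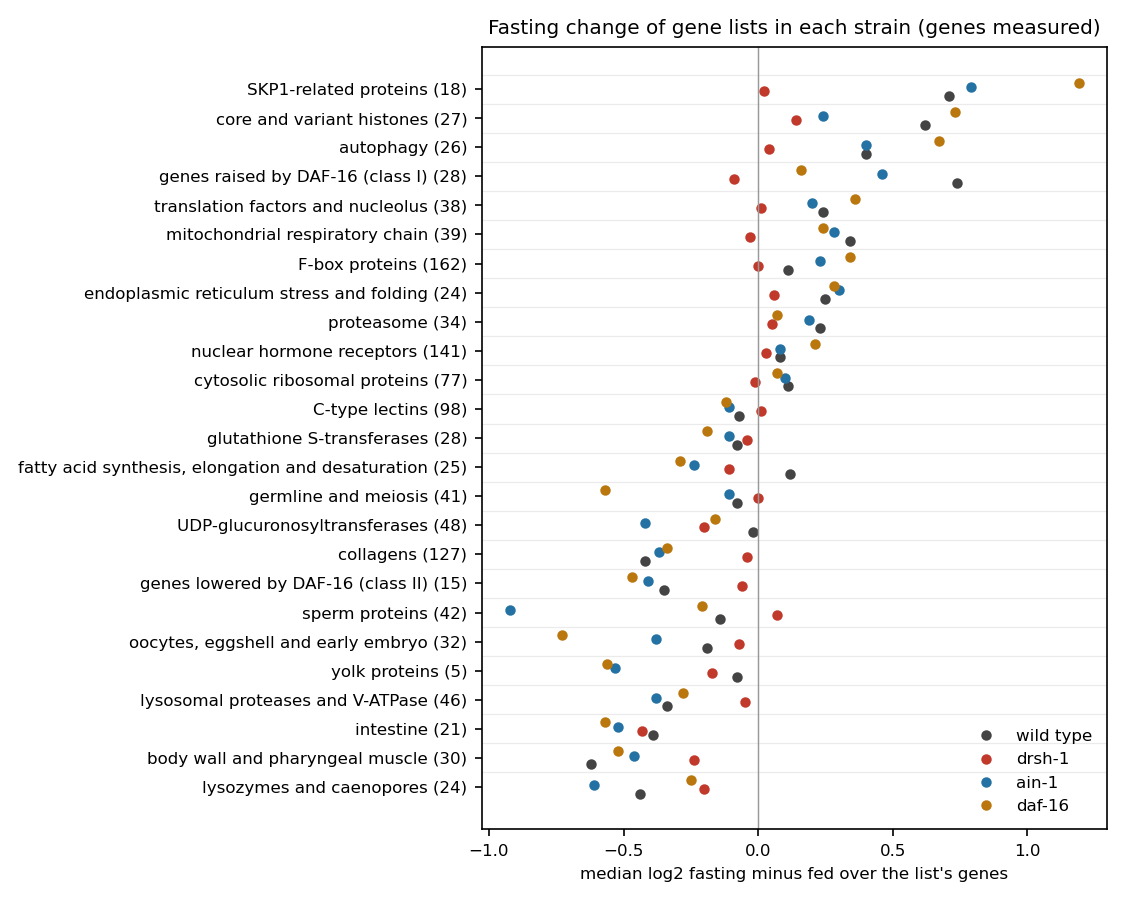
Median log2 change, fasting minus fed, of the genes of each list that passed camera over the 4 strains, with 1 point per strain and the number of genes measured in brackets. SKP1-related genes lie at 0.71 in wild type, 0.02 in drsh-1, 0.79 in ain-1 and 1.19 in daf-16.

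Each strain was then set beside the others to ask whether the fasting response needed DRSH-1, AIN-1 or DAF-16. The drsh-1 animals showed few of the rises of the other strains, and smaller falls. For the 150 probe sets at least 4-fold lower in the other strains, the fed drsh-1 array was already lower. In the median it lay 0.55 of the way from the others' fed mean to their fasting mean. The fasting drsh-1 array lay 1.04 of the way, so the median faller ended near the others' fasting level. The acyl-CoA synthetase gene acs-2, which prepares fatty acids for oxidation, went from 54 fed to 1878 fasting in wild type, from 84 to 1347 in ain-1 and from 67 to 841 in daf-16, but was 244 and 211 in drsh-1. The alcohol dehydrogenase gene adh-1 went from 191 to 3848 in wild type, from 54 to 3241 in ain-1 and from 63 to 1789 in daf-16, with 358 and 293 in drsh-1. The small heat shock gene hsp-16.2 went from 26 to 186 in wild type, with 116 and 125 in drsh-1. Other risers of wild type already stood high in fed drsh-1 animals: far-7 at 153 (20 to 215 in wild type), dct-7 at 265 (36 to 235), Y43C5A.3 at 385 (49 to 339) and F45D3.4 at 2173 (596 to 2330). On the falling side, sysm-1 went from 598 to 44 in drsh-1 and dod-19 from 2707 to 1053, where wild type had 4401 and 42. The gene bcf-1 was at 12 in both drsh-1 arrays, against 1566 fed and 19 fasting in wild type.

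Changes of at least 2-fold numbered 407 up and 530 down in wild type, 5 and 164 in drsh-1, 430 and 551 in ain-1, and 1131 and 791 in daf-16. These are descriptions of single pairs of arrays with no test, and under the additive model (median residual SD 0.1466 on the log2 scale) a difference of 2 arrays has an SD of 0.21. The highest changes were acs-2 (4.76), adh-1 (4.23), the lysozyme gene ilys-3 (4.19), T16G1.7 (3.55) and aqp-1 (3.43) in wild type, and adh-1 (5.53), ilys-3 (4.90), acs-2 (3.77), aqp-1 (3.07) and hsp-16.2 (2.71) in ain-1. In drsh-1 they were trx-3 (1.26), T22B7.3 (1.2), ilys-2 (1.05), lips-13 (1.05) and pals-27 (0.93). In daf-16 they were T22F3.11 (4.73), adh-1 (4.52), the flavin monooxygenase gene fmo-2 (4.06), Y53F4B.45 (4.06) and acs-2 (3.37). The genes with the lowest changes in wild type were dod-19 (−6.24), sysm-1 (−6.22), bcf-1 (−5.48), hrg-11.2 (−5.47) and ilys-5 (−5.25). In drsh-1 they were ilys-5 (−3.85), col-143 (−3.72), ctsa-1.2 (−3.66), sysm-1 (−3.35) and T21H3.1 (−3.34). In ain-1 sysm-1 (−6.05), dod-19 (−5.68), ilys-5 (−5.58), ctsa-1.2 (−5.02) and C17H12.8 (−4.79) were lowest, and in daf-16 bcf-1 (−5.68), hrg-11.2 (−5.45), sysm-1 (−5.19), ilys-5 (−5.15) and dod-19 (−5.06).

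Across probe sets, which are not independent replicates, the fasting change in drsh-1 had a Pearson correlation of 0.534 with that in wild type (Spearman 0.171) with a slope of 0.258 by least squares and 0.483 by the reduced major axis. For ain-1 the correlation was 0.887 (Spearman 0.804, slopes 0.885 and 0.997), and for daf-16 it was 0.777 (Spearman 0.669, slopes 0.983 and 1.266). Choosing probe sets in the strains outside each comparison avoids favouring wild type. For ain-1 and daf-16 that choice includes drsh-1, which rose little. Fewer risers were then chosen (204 and 49, against 718), so shares compare with wild type in the same choice, not between mutants. Of 718 at least 2-fold higher in the mean of ain-1 and daf-16, 42.6% were so in wild type and 0.4% in drsh-1, with medians of 0.93 and 0.08. Of 509 at least 2-fold lower in that mean, 79.4% were so in wild type and 28.5% in drsh-1, with medians of −1.56 and −0.59. For ain-1, of 204 chosen as higher in the mean of drsh-1 and daf-16, 75% were so in wild type and 82.4% in ain-1, and of 292 chosen as lower 91.1% and 91.4%. For daf-16, with the choice made in the mean of drsh-1 and ain-1, the shares were 89.8% and 87.8% of 49 chosen as higher, and 93.1% and 89.5% of 304 chosen as lower. With 1 array per group, a model with a separate fasting change for every strain leaves 0 residual degrees of freedom. Testing each strain's change against the mean of the other 3, an alternative added after seeing the data, limma with 2 residual degrees of freedom gave 0 calls in each strain, with 178 unadjusted for wild type, 2070 for drsh-1, 148 for ain-1 and 2749 for daf-16. By chance 789 would be expected at an unadjusted p under 0.05. When wild type or ain-1 is tested, the differing drsh-1 and daf-16 changes enter the residual.

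**Figure D3:**
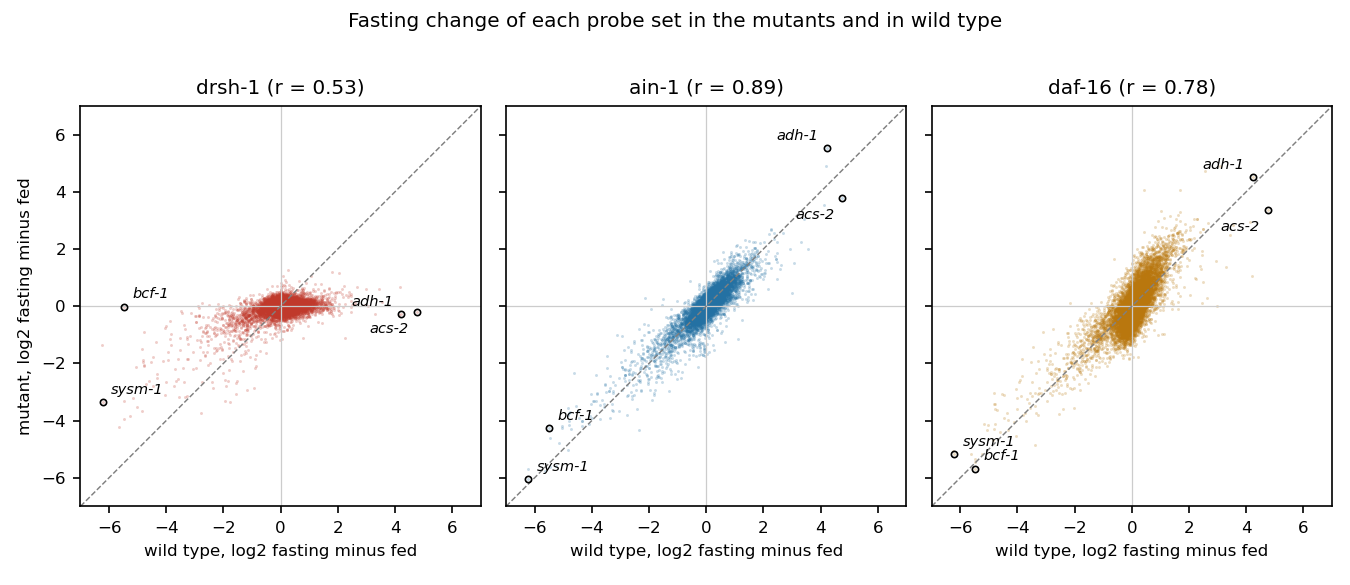
Log2 change, fasting minus fed, of each probe set in the 3 mutants (vertical axes) against the change in wild type (horizontal axes), with 1 point per probe set and a dashed line of equal change. The gene acs-2 lies at 4.76 in wild type and −0.20 in drsh-1, and the correlations are 0.53, 0.89 and 0.78.

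In the model without the drsh-1 arrays, single genes passed that did not pass over 4 strains. There acs-2 rose by 3.97 ± 0.26 (limma, adjusted p = 0.00067), adh-1 by 4.76 ± 0.25 (0.00035), hsp-16.2 by 2.67 ± 0.18 (0.00067), T16G1.7 by 2.80 ± 0.28 (0.0024) and the isocitrate lyase and malate synthase gene icl-1 by 1.63 ± 0.19 (0.0039). The insulin-like gene ins-7 had a change of −2.47 ± 0.19 (0.001) and bcf-1 one of −5.15 ± 0.28 (0.00038). Over 4 strains, acs-2 had 2.93 ± 0.73 (adjusted p = 0.072), adh-1 3.50 ± 0.87 (0.072), hsp-16.2 2.03 ± 0.46 (0.064) and T16G1.7 2.13 ± 0.50 (0.068).

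Gene lists were described in single strains by the percentile of each median among 10000 random lists of the same size and expression, with no test between strains. The random lists hold genes drawn singly, without the correlation between members of a real list, and each value is 1 pair of arrays. A percentile of 0 or 100 is therefore a description and not a p-value. Class I genes of DAF-16 had a median change of 0.74 in wild type (percentile 100), −0.09 in drsh-1 (percentile 0.7), 0.46 in ain-1 and 0.16 in daf-16. Autophagy genes had 0.40 in wild type (percentile 100), 0.04 in drsh-1 (percentile 94.6), 0.40 in ain-1 and 0.67 in daf-16. Respiratory chain genes had 0.34 in wild type (percentile 100) and −0.03 in drsh-1 (percentile 37). Histones had 0.62 and 0.14, both at percentile 100. Intestinal genes had −0.39 in wild type and −0.43 in drsh-1, both at percentile 0. Collagens had −0.42 in wild type and −0.04 in drsh-1, both also at percentile 0, and in drsh-1 22 of the 127 were at least 2-fold lower. Sperm genes stood at −0.92 in ain-1, with 20 of 42 at least 2-fold lower, and at −0.14 in wild type.

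The daf-16 fasting array differed from the other 7 in its controls, as well as in some gene groups. Its ratio of 3-prime to 5-prime catalase signal was 3.4, against 1.47 to 1.79 on the others, and its signal of the bacterial spike dap was 178 against 70.1 to 91.8. On that array oocyte genes changed by a median of −0.73, against −0.19 in wild type, and germline genes by −0.57, against −0.08. SKP1-related genes changed by 1.19 in daf-16 against 0.71 in wild type. The ferritin gene ftn-1 went from 66 to 684 in daf-16 and from 510 to 1134 in wild type, while ilys-3 went from 28 to 75 in daf-16 and dod-6 from 158 to 71. The response of ain-1 exceeded that of wild type downward for the acyl-CoA dehydrogenase gene acdh-1 (−4.33 against −2.36) and for msp-76, a major sperm protein gene (452 fed and 132 fasting in ain-1, 81 and 83 in wild type).

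Many probe sets differed between drsh-1 and wild type in the mean over both food conditions. The genes named by rank were required to differ in the same direction fed and fasting. The lysozyme genes ilys-2 (12 fed and 43 fasting in wild type, 938 and 1963 in drsh-1) and ilys-3 (38 and 975 against 5308 and 8548) were higher by 5.08 ± 0.17 (33.8-fold, adjusted p = 0.00013) and 4.86 ± 1.02 (29.1-fold, adjusted p = 0.029). The sodium-calcium exchanger gene ncx-6 was at 9 and 10 in wild type and 399 and 364 in drsh-1 (3.96 ± 0.11, adjusted p = 5.7e-05), and the cell fusion gene eff-1 at 17 and 26 against 448 and 329 (3.42 ± 0.26, adjusted p = 0.0014). Lower genes included pud-4 (442 and 581 in wild type, 12 and 15 in drsh-1, −4.16 ± 0.46, adjusted p = 0.0042), and the hexosaminidase gene hex-1 (675 and 2263 against 87 and 89, −3.59 ± 0.48, adjusted p = 0.0072). Values below 15.71, the level of the filter, lie near background, so for ilys-2, ncx-6 and pud-4, and for acr-7 below (12 and 11 in wild type), the pseudocount sets the size and rank of the difference.

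In all, 1260 probe sets were higher and 590 lower in drsh-1 than in wild type (934 and 466 genes), with 4543 at an unadjusted p under 0.05. The remaining genes named by rank were F40D4.13 (3.86 ± 0.21), C38D9.2 (3.84 ± 0.63), C50F7.5 (3.36 ± 0.32) and the acetylcholine receptor gene acr-7 (3.35 ± 0.10) on the higher side. On the lower side they were D1086.10 (−3.85 ± 0.22), the lectin gene clec-52 (−3.83 ± 0.21), the lysozyme gene lys-4 (−3.76 ± 0.30), the aspartyl protease genes asp-3 (−3.29 ± 0.22) and asp-13 (−3.28 ± 0.29), and Y73F4A.1 (−3.15 ± 0.38). Leaving out the wild-type fed array gave 218 higher and 115 lower, and leaving out the wild-type fasting array 99 and 46. Without the drsh-1 fed array there were 796 and 577, without the drsh-1 fasting array 1259 and 675, and without food in the model 463 and 90.

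**Figure D4:**
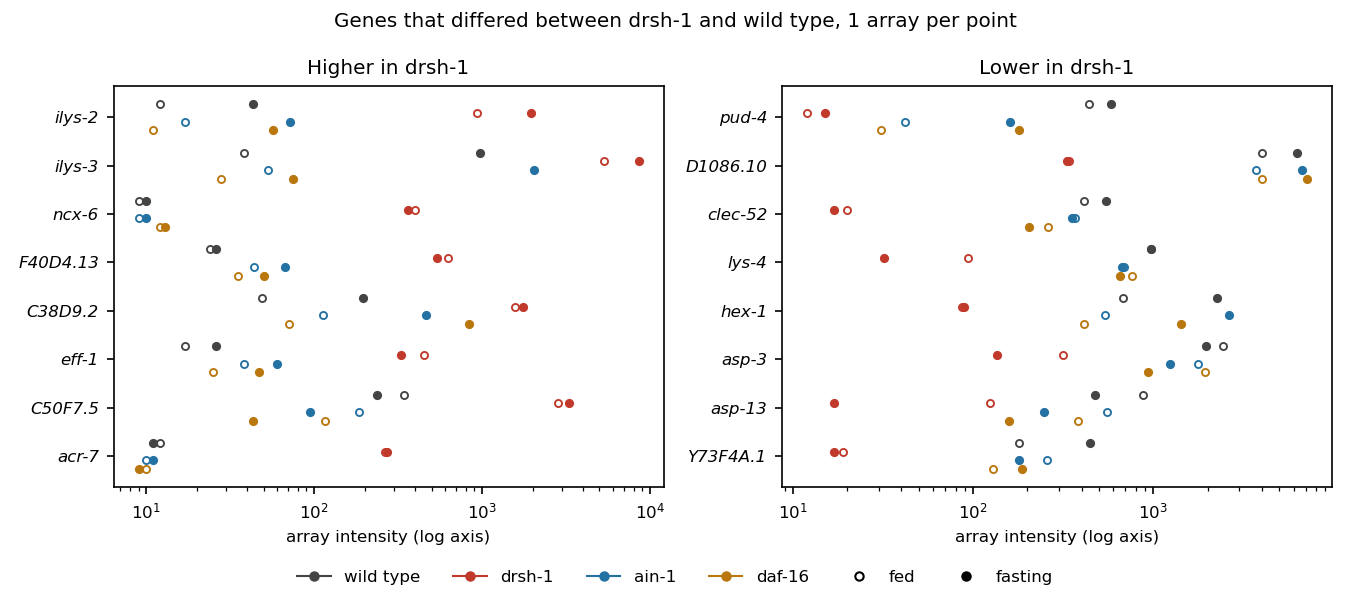
Array intensity on a log axis of the 8 highest and 8 lowest genes called between drsh-1 and wild type, with 1 open point (fed) and 1 filled point (fasting) per strain. In both food conditions ncx-6 lies at 399 and 364 in drsh-1 and at 9 and 10 in wild type, and pud-4 at 12 and 15 against 442 and 581.

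Known microRNA targets and genes of the microRNA machinery were among those that changed in drsh-1. Of 13 targets of lin-4 and let-7 family microRNAs, 3 rose and 1 fell (7 and 2 adjusted over the list alone). The zinc finger gene hbl-1 went from 90 fed and 101 fasting in wild type to 446 and 512 in drsh-1 (2.15 ± 0.16, adjusted p = 0.0014), and the nuclear receptor genes nhr-25 and daf-12 were higher by 1.90 ± 0.24 (0.0064) and 1.17 ± 0.16 (0.0084). The value of lin-41 was 0.96 ± 0.25 (adjusted p = 0.053), and sdz-24 was the member that fell (−0.52). The list passed fry (adjusted p = 0.0087) but not camera (adjusted p = 0.074, and adjusted p = 0.68 with an estimated correlation). Of 24 genes of the microRNA machinery, 4 rose and 2 fell (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.062 and adjusted p = 0.71 with an estimated correlation. The Argonaute gene alg-1 was higher by 1.18 ± 0.19 (adjusted p = 0.012) and pash-1, which encodes the partner of Drosha, by 1.14 ± 0.16 (0.0079), while drsh-1 itself was at −2.67 ± 0.22 (0.0019) on 1 probe set, the other being 5.78 and 5.19 times the wild-type level.

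Aminoacyl-tRNA synthetases and translation factors were higher and collagens, lectins and lysosomal genes lower in drsh-1 by camera with a preset correlation. Of 34 aminoacyl-tRNA synthetases 12 rose (24 adjusted over the list alone), among them glp-4, the valyl-tRNA synthetase (1.15 ± 0.16), iars-1 (1.07 ± 0.14) and tars-1 (0.81). That list passed camera (adjusted p = 1.7e-08) and fry (adjusted p = 0.0087), with adjusted p = 0.43 with an estimated correlation. Of 38 translation factors 7 rose (12 adjusted over the list alone, camera adjusted p = 1.2e-05, and adjusted p = 0.70 with an estimated correlation). The 77 cytosolic ribosomal proteins did not pass (median 0.05, 3 higher, 0 adjusted over the list alone, camera adjusted p = 0.12, fry adjusted p = 0.51). Of 13 genes of the AP-1 and KGB-1 stress kinase pathway 6 rose (7 adjusted over the list alone, camera adjusted p = 6.8e-05, and adjusted p = 0.46 with an estimated correlation), including the phosphatase gene vhp-1 (1.67 ± 0.23) and svh-2 (1.56 ± 0.17). Of 141 nuclear hormone receptors 19 rose and 2 fell (23 and 3 adjusted over the list alone, adjusted p = 0.0029, and adjusted p = 0.76 with an estimated correlation), with nhr-3 at 2.68 ± 0.27. Collagens had 35 lower and 1 higher of 127 (53 and 2 adjusted over the list alone, adjusted p = 1.0e-17, and adjusted p = 0.70 with an estimated correlation), with col-143 at −2.89 ± 0.32. Among C-type lectins 18 of 98 fell and 1 rose (22 and 2 adjusted over the list alone, adjusted p = 1.4e-08, and adjusted p = 0.68 with an estimated correlation), and 8 of 46 lysosomal genes fell (11 adjusted over the list alone, adjusted p = 8.5e-06, and adjusted p = 0.43 with an estimated correlation). Fry passed 0 of these last 6 lists. The synthetase, translation factor, collagen, lectin and lysosomal lists were not particular to drsh-1. With a preset correlation camera called them in the same direction in ain-1 and in daf-16. Their adjusted p was 6.0e-16 to 0.0048 in ain-1 and 2.6e-05 to 0.034 in daf-16. All 3 comparisons use the same wild-type arrays. The AP-1 and nuclear hormone receptor lists were not called in those mutants.

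Tissue lists were also called by camera in drsh-1. Germline genes were higher (41 measured, median 0.21, 3 rose, adjusted p = 0.016, and adjusted p = 0.85 with an estimated correlation). Oocyte genes were lower (32 measured, median −0.23, 3 fell, adjusted p = 0.0066, and adjusted p = 0.85 with an estimated correlation), as were cell cycle genes (35 measured, median −0.20, 2 fell, adjusted p = 0.0015, and adjusted p = 0.71 with an estimated correlation). By camera with a preset correlation oocyte genes were also lower in ain-1 and daf-16 (adjusted p = 1.7e-05 and 0.0029), and cell cycle genes in ain-1 (adjusted p = 0.014). A change in tissue content was not tested. In all, camera with a preset correlation called 6 lists higher and 11 lower, and 0 were called with an estimated correlation.

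Few genes separated ain-1 from wild type. The antimicrobial peptide gene cnc-4 was at 239 fed and 204 fasting in wild type and 1335 and 869 in ain-1 (2.21 ± 0.17, adjusted p = 0.024). The ABC transporter gene haf-3 went the other way, from 298 and 282 to 19 and 19 (−3.13 ± 0.19, adjusted p = 0.017), as did F57A10.4, from 316 and 294 to 15 and 19 (−3.29 ± 0.24, adjusted p = 0.024). The CARMIL homologue crml-1, named after its values were seen, was at −1.68 ± 0.16 and −1.70 ± 0.14 on 2 probe sets (adjusted p = 0.045 and 0.035). Large differences that did not pass were srlf-34 (2.63 ± 0.40, adjusted p = 0.19), C30F12.3 (2.19 ± 0.52, 0.48), cnc-2 (1.78 ± 0.33, 0.28), pud-3 (−2.50 ± 0.28, 0.091) and pud-4 (−2.38 ± 0.46, 0.34).

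In limma 1 probe set was higher and 7 lower in ain-1, with 923 at an unadjusted p under 0.05 where 789 were expected. Leaving out any of the wild-type or ain-1 arrays gave 0 calls, and arrayWeights, which weighted the ain-1 pair at 3.55, gave 264 higher and 233 lower. Of 22 genes on the list of epidermal antimicrobial peptides 1 rose (13 higher and 1 lower adjusted over the list alone), with a median of 0.92 and cnc-6 at 1.56 ± 0.32 and abf-2 at 1.54 ± 0.34 (adjusted p = 0.37 and 0.47). Whole animals were measured, so the tissue in which a listed gene differed is not known. The 42 sperm genes had 0 calls over all genes and 24 higher adjusted over the list alone, with a median of 0.66. Their highest member msp-55 was at 826 in fed and 264 in fasting ain-1 animals, and at 152 and 142 in wild type. Muscle genes had a median of −0.44 and 8 of 30 lower adjusted over the list alone, and collagens −0.17 and 7 of 127. The camera adjusted p values were 2.7e-11 for antimicrobial peptides, 3.1e-14 for sperm, 1.7e-13 for muscle and 6.0e-16 for collagens, and these were adjusted p = 0.43, 0.70, 0.46 and 0.70 with an estimated correlation. In fry 0 lists passed. Of all lists, 4 were higher and 14 lower by camera with a preset correlation, and 0 with an estimated correlation.

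Genes that DAF-16 is known to activate were lower as a list in daf-16 than in wild type, although no single gene passed. This list passed camera with a preset correlation (adjusted p = 3.0e-15) but not fry (adjusted p = 0.17), and had adjusted p = 0.46 with an estimated correlation. The metallothionein gene mtl-1 was at 320 fed and 1171 fasting in wild type and 11 and 28 in daf-16 (−4.19 ± 0.51, adjusted p = 0.098). Its value of 11 lies below 15.71, the level of the filter, so the pseudocount limits the size of that difference. The values of dod-6 were 1008 and 1937 against 158 and 71 (−3.52 ± 0.47, adjusted p = 0.11), those of lys-7 7530 and 704 against 1539 and 38 (−3.01 ± 0.47, 0.14), and pho-11 stood at −2.99 ± 0.39 (0.11). On the other side were F42A10.7 (1.58 ± 0.73, adjusted p = 0.61), F53A9.8 (1.57 ± 0.36, 0.29), ins-7 (1.5 ± 0.63, 0.57) and srlf-34 (1.47 ± 0.40, 0.40). Among the 28 class I genes the median was −0.80, with 0 calls over all genes and 12 lower and 1 higher adjusted over the list alone, and pck-1 at −1.79 ± 0.26 and fat-5 at −1.73 ± 0.26.

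Limma called 0 probe sets higher and 0 lower in daf-16, with 1385 at an unadjusted p under 0.05 and a smallest adjusted p of 0.067, and arrayWeights also called 0. Muscle genes had a median of −0.62 and 17 of 30 lower adjusted over the list alone, with tnt-2 at −1.68 ± 0.28 and unc-54 at −1.29 ± 0.23 (adjusted p = 0.17 and 0.20 over all genes). UDP-glucuronosyltransferases (median −0.23), cytochromes P450 (−0.17) and glyoxylate cycle genes (−0.32) were also lower, and F-box genes (0.23), translation factors (0.24) and aminoacyl-tRNA synthetases (0.23) higher by camera. The camera adjusted p was 1.5e-22 for muscle, which had adjusted p = 0.46 with an estimated correlation, and the other lists ran from 6.9e-07 to 0.00089, with adjusted p = 0.46 to 0.71 with an estimated correlation. Fry passed 0 lists, and camera with a preset correlation called 3 higher and 16 lower, and 0 with an estimated correlation. These comparisons include the daf-16 fasting array, whose catalase ratio was 3.4.

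The mutants were compared for shared genes, bearing in mind that the 3 comparisons use the same wild-type arrays. Of the 8 calls in ain-1, 5 were also among the 1850 calls in drsh-1 in the same direction, where independent lists would share 0.34. They were cnc-4, F57A10.4 and 3 probe sets with no single gene symbol here. In drsh-1 cnc-4 was at 604 fed and 429 fasting, and F57A10.4 at 156 and 133. With 1 wild-type array per food the controls could not be split, and part of the excess over that value can come from them. The differences from wild type in drsh-1 and ain-1 had a correlation across probe sets of 0.44, against 0.5 in simulated groups with no effect, and a covariance of 0.059 against 0.019. Between arrays that share no control, the fed difference of drsh-1 and the fasting difference of ain-1, the correlation was 0.38, and 0.21 the other way round. For ain-1 and daf-16 these were 0.52 (covariance 0.038), and 0.18 and 0.34 between arrays that share no control, so the correlation was not particular to drsh-1 and ain-1. For drsh-1 and daf-16 they were 0.23 (covariance 0.036), and 0.24 and 0.03. The daf-16 mutant shared 0 calls with either, since it had 0 calls.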

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

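Of the tests in this part, those of the drsh-1 and daf-16 responses, of each strain against the other 3 and of the control ratios were chosen only after the result was seen. So was keeping only the splits of the arrays that part every pair.

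Some gene lists had a fasting change in 1 strain apart from the mean of the other 3 by camera with a preset correlation, but not by camera with an estimated correlation or by fry. The single strain is 1 pair of arrays in each test, so these p-values cannot separate a strain from its pair. In drsh-1 the median difference was −0.67 for class I genes of DAF-16 (adjusted p = 0.016), −1.04 for SKP1-related genes (adjusted p = 0.00029) and 0.52 for sperm genes (adjusted p = 1.3e-05). For sperm genes the other 3 strains include ain-1, whose median was −0.92, and the median of drsh-1 minus wild type was 0.21. In ain-1 the median difference was −0.72 for sperm genes (adjusted p = 1.3e-45), and in daf-16 it was −0.57 for oocyte and eggshell genes (adjusted p = 3.3e-09). None passed with an estimated correlation (each adjusted p = 0.89 with an estimated correlation). Fry called 0 lists in any strain (smallest adjusted p = 0.35).

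On the daf-16 fasting array several controls lay outside the range of the other 7 arrays. The ratio of 3-prime to 5-prime signal was 3.4 for catalase (1.47 to 1.79 on the others) and 7.61 for ubiquitin (6.1 to 6.74). The bacterial spike dap had an intensity of 178 at its 3-prime end (70.1 to 91.8) and 153 in its middle (66.7 to 84.3), and the hybridization spike bioC was at 290 (190 to 234).

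The calls for fasting over the 4 strains were weighed against chance. Only 8 splits part the fed and fasting array of every strain as the real one does, which is too few for a share under 0.05. The real one gave 523 calls, 1 of 8 gave as many, and the highest other gave 0. In each other split the fasting change itself enters the residual.

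The drsh-1 pair showed few of the rises seen in the other strains. A fasting array of animals that had not been fasted is argued against: the 150 probe sets at least 4-fold lower in the other strains had a median change of −1.33 in drsh-1 (95% bootstrap interval −1.55 to −1.14), where the others had −2.62. The intervals in this paragraph resample probe sets of 1 pair of arrays. Those are not independent, so the intervals hold no spread between animals or arrays. The median ratio of drsh-1's change to that of the others was 0.40 for 481 fallers and 0.06 for 566 risers, a difference of 0.34 (interval 0.30 to 0.38). A response smaller by the same factor in both directions would give equal ratios. This difference is the pattern itself, and a weaker or shorter fast need not scale rises and falls alike. Such a fast therefore stays open. Also open is how far fed drsh-1 animals already stood at the fasting level. The median position of 35 risers between the fed (0) and fasting (1) level was 0.39 on the fed drsh-1 array, with an interval of 0.02 to 0.53. It was 0.36 on the fasting drsh-1 array, and 0.36 for the 566 risers on the fed one. The 150 fallers had a median position of 0.55 on the fed drsh-1 array and 1.04 on the fasting one. The median riser thus lay between the levels on both arrays, while far-7, dct-7, Y43C5A.3 and F45D3.4 were near or above the wild-type fasting level when fed. With 1 array for each food this cannot be told apart. Loss of microRNA processing, which the design names, may be behind the pattern, but 1 pair of arrays cannot separate it from other differences of that strain or pair.

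The daf-16 pair held the most 2-fold changes, 1922 of 15783 probe sets. Of these, 96.6% changed in the same direction in both wild type and ain-1 (interval 95.7 to 97.4), which argues against changes that are noise alone. That interval counts probe sets as independent and holds no spread between arrays. Noise added to a shared response would also leave most directions the same. The share therefore cannot tell whether noise raised the number above that of the other strains, and this stays open. Lower RNA quality of the fasting array stays open: 2 of 4 ratios of 3-prime to 5-prime signal lay clearly above the other arrays, while those of GAPDH (1.2, others up to 1.19) and actin (2.11, others up to 2.06) did not, so it cannot be told apart. All 4 ratios were highest on that array, and the values of 1.19 and 2.06 came from the fed daf-16 array. Loss of DAF-16 may also enlarge the response, which was not tested.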

How the results depend on the processing

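Here the fits without the drsh-1 pair for the other mutants and without the daf-16 fasting array were chosen only after the result was seen. Among 56 named gene results under 766 alternatives, 0 changed direction, 665 kept their side of the threshold, 95 lost it and 6 gained it, and the cause was not tested unless given below. For fasting over the 4 strains, higher calls (68) became 125 with the 50% filter, 160 with arrays centred on medians, 111 with pseudocount 1, 39 with pseudocount 64, 23 without trend, 3680 with arrayWeights and 4 without the strain block. Lower calls (455) became 295 without trend, 2662 with arrayWeights and 125 without the strain block. Leaving out each strain gave 3 to 2361 higher and 94 to 1415 lower. Both high ends came without drsh-1, whose differing response counted as error. The drsh-1 calls (1260 and 590) became 463 and 90 without the food block, and ranged from 99 to 1259 and from 46 to 675 with a drsh-1 or wild-type array left out. Without the daf-16 fasting array they were 1670 and 847. The ain-1 calls (1 and 7) became 264 and 233 with arrayWeights, 0 and 1 without the food block, 2 and 3 without the daf-16 fasting array, and 0 and 0 with any wild-type or ain-1 array left out. Lower ain-1 calls were 4 without trend and 3 without the drsh-1 pair. The daf-16 calls (0 and 0) were 0 to 1 each way with an array left out, and lower calls were 1 without the filter, 2 with pseudocount 1 and 1 without the drsh-1 pair. Counts at 2-fold with pseudocount 64 were 194 higher in wild type, 3 in drsh-1, 188 in ain-1, and 651 higher and 456 lower in daf-16. At 3-fold they were 99 and 261 in wild type, 0 and 81 in drsh-1, 95 and 266 in ain-1, and 402 and 251 in daf-16, fewer by construction. Choosing probe sets by wild type gave 61.4% higher and 77.9% lower in ain-1 and 72.8% lower in daf-16. That choice favours wild type and also takes other probe sets, and which of these moved the shares was not tested. Lists called were 0 in each comparison and direction with an estimated correlation. By fry they were 0 higher and 3 lower in fasting, 2 and 0 in drsh-1, 0 and 0 in ain-1, and 0 and 0 in daf-16. Of 176 rounded list medians, 7 near 0 (−0.03 to 0.06) changed sign from the deposited scaling under quantile normalization or centring on medians. Peroxisomal beta-oxidation in fasting, at 0 as deposited, is not counted among them and was 0.02 under quantile normalization and −0.02 under centring. The text gives none of these lists a direction in those comparisons. Without the filter 12 lists were higher in drsh-1 (6 with it). At an adjusted p under 0.01 drsh-1 and ain-1 shared 0 calls. Signal over background limits dim genes: the probe sets left out lay below an intensity of about 15.71, where a pseudocount of 16 compresses change.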

Other observations

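In this part the probe sets changed in 3 strains, the correlations of fed drsh-1 animals with fasting changes and the gene neighbours were chosen only after the result was seen. Further gene lists held single genes that differed between drsh-1 and wild type. Of 71 neuropeptide genes 7 rose and 1 fell (7 and 3 adjusted over the list alone), with nlp-16 at 2.23 ± 0.27 and flp-5 at 1.38 on the higher side and nlp-40 at −1.67 ± 0.13 on the lower. The neuropeptide list did not pass camera (adjusted p = 0.27, and adjusted p = 0.85 with an estimated correlation). Of 48 UDP-glucuronosyltransferases 10 fell and 5 rose (13 and 8 adjusted over the list alone), and of 24 lysozymes and caenopores 9 fell and 5 rose (12 and 5 adjusted over the list alone), so that both families were split. Of 17 lipase genes 3 fell (4 adjusted over the list alone), with a median of −0.51, camera adjusted p = 0.013 and adjusted p = 0.46 with an estimated correlation. Of 24 genes of endoplasmic reticulum stress 4 rose, also adjusted over the list alone, with a median of 0.24, camera adjusted p = 0.016 and adjusted p = 0.71 with an estimated correlation.

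In fasting over the 4 strains, the acyl-CoA dehydrogenase gene acdh-1 fell by 2.84 ± 0.38 (adjusted p = 0.015) and the small heat shock gene hsp-17 by 2.15 ± 0.26 (adjusted p = 0.011), while acs-2 and hsp-16.2, of the same lists, did not pass over the 4 strains and were higher without the drsh-1 arrays. Of 234 probe sets at least 2-fold higher in wild type, ain-1 and daf-16, 3 were so in drsh-1, with a median change of 0.07 against 1.65. Of 345 at least 2-fold lower in those strains, 136 were so in drsh-1, with −0.81 against −1.87.

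Before any fasting, the difference between fed drsh-1 animals and fed animals of another strain correlated across probe sets with the fasting change of a strain that shares no array with it. The Pearson correlation ran from 0.4 to 0.52 over 6 such pairings, and Spearman's from 0.32 to 0.44, and probe sets are not independent replicates. The fed and fasting drsh-1 arrays correlated at 0.989 over probe sets, against 0.953 in wild type, 0.953 in ain-1 and 0.926 in daf-16.

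The genes haf-3 and F57A10.4, both low in ain-1, lie on chromosome V with 1 protein-coding gene between them in WBcel235, and pud-3 and pud-4 are neighbours on V with 0 between them. For pud-3 the difference from wild type was −3.06 in drsh-1 (adjusted p = 0.0024), −2.50 in ain-1 (0.091) and −2.93 in daf-16 (0.067), and for pud-4 −4.16 (0.0042), −2.38 (0.34) and −2.45 (0.21). The 3 comparisons share the wild-type arrays.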
